A study of Arabidopsis thaliana with 9 samples.

How the data were processed

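RNA from Arabidopsis thaliana root tips of 2 to 3 mm was measured in 9 libraries, 1 for each of 9 groups. Per the labels, RNA was extracted with TRIzol and made into TruSeq mRNA libraries that do not keep the strand, and the groups were 3 genotypes (wild type Col-0, stop1 and almt1) under 3 conditions each. The deposited values are raw counts per locus. The submitters' processing notes name TopHat2 and HTSeq without versions and the TAIR10 genome. Each library listed 33602 loci and 5 summary lines for reads not assigned to 1 gene. The reference at hand was TAIR10.1, used for gene names and for overlaps between neighbouring loci and not for positions; 32835 loci matched it. One label conflict was found: the title of the stop1 malate sample reads as high phosphate while its characteristics give low phosphate with malate, and the characteristics were followed. No sample column was left without a group.

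Gene counts ranged from 20619740 to 37189056 per library. A count of 0 was read as at most 3 counts, which is 0.0767 to 0.147 CPM in the different libraries. The intervals and floors cover counting error only. Because the libraries do not keep the strand, values at 5112 loci that overlap another locus, with 22.4% to 23.6% of the counts, are uncertain as to which gene the reads came from.

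Groups had no replicates, so each test borrowed its spread from terms left out of a model. All were made with edgeR 4.0.16 quasi-likelihood tests (TMM scaling, robust dispersion, a threshold of 0.05 on Benjamini-Hochberg adjusted p-values). Genes first passed filterByExpr with a minimum count of 10 and a minimum total of 15, in R 4.3.3 with limma 3.58.1. A prior count of 2 entered only the log2 CPM values behind camera, principal components, correlations and list medians of single-library pairs. It was not set for the fitted fold changes. Low against high phosphate over 3 genotypes used 6 libraries with genotype as a block (20948 genes, 2 residual degrees of freedom). The other fits used 9 libraries and 21229 genes: with a stop1 against almt1 term for comparisons within genotypes (2 residual degrees of freedom), and without it for mutants against wild type (3 residual degrees of freedom). In these, stop1 and almt1 stand in for replicates of 1 mutant class, and the lone wild-type libraries are assumed to vary as the mutants do. The SE beside a fitted log2 fold change is its absolute value divided by the square root of the quasi-likelihood F statistic. The p-values and these SE measure the spread between these samples and not between independent growths of each group.

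There were 8 designed fits and 13 comparisons of single libraries. The latter give a log2 ratio of TMM-scaled counts with an exact conditional binomial 95% interval, and count genes at least 2-fold apart whose interval excludes equality; they carry no p-value. A list median was set against 10000 random lists matched for size and expression. Gene lists numbered 16 with 261 genes and were fixed before the data were examined, as were the groups, comparisons, tests and rule for naming genes. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. No camera call held with an estimated correlation in any fit. The 16 lists cover STOP1 and malate genes, the local response of the tip to low phosphate, systemic phosphate starvation, iron deficiency, iron storage, cell wall peroxidases, cell wall extension, the stem cell niche, the cell cycle, root hairs, endodermis and xylem, root cap, shoot photosynthesis, wounding and touch, hypoxia and heat, and reference genes. Where members moved both ways, median, mean and camera direction differed in sign. This held for peroxidases over 3 genotypes, for the response difference, with malate, with low iron, at high phosphate and in malate mutants against low-iron wild type. Cell wall extension and cell cycle did so over 3 genotypes, and reference genes in wild type. Root hairs did so with malate and in mutants against wild type at low phosphate. Stem cell niche did so with low iron, hypoxia and heat with low iron and at high phosphate, and iron storage at high phosphate, and these lists also in malate mutants against low-iron wild type.

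Genes were named by a rule: STOP1 and ALMT1 first, then per fit the 10 highest and 10 lowest called genes with at least 5 CPM in a library of the contrast and 1 direction in each mutant, per single-library pair the 5 highest and 5 lowest, and per list up to 4 members with the largest change, of which the text gives a selection. Further list members named in the text, and AT2G01021, were chosen after their values were seen.

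On simulated data with 200 changed genes, the fits recovered 15% to 81% of 2-fold and 82% to 100% of 4-fold changes, and 6.9% to 21.1% of calls were false, above the nominal 5% in each fit. The 95% counting intervals covered the simulated ratio in 96.8%, 95.4% and 95.2% of cases at mean counts of 5, 50 and 500.

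Alternatives set before the data were examined were RLE size factors, library size alone for the pairs, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, the genotype term added or removed, leaving out each mutant library or each genotype in turn, at least 50 counts for the pairs, and genes with at least 5 CPM for correlations. A fit of the 6 libraries at high and low phosphate alone, the comparison of malate mutants with low-iron wild type and a count of shared calls were chosen after seeing the data. Replicate growths and tissues other than the root tip were not analysed here.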

Results

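Root tips of 2 to 3 mm were cut from Arabidopsis thaliana seedlings 5 days after germination. Their polyadenylated RNA was sequenced to ask how tips respond to scarce phosphate in wild type and in mutants that the series title describes as insensitive to it. There were 9 libraries, 1 for each of 9 groups. Wild type (the Col-0 accession) and the mutants stop1 and almt1 were each grown at 1 mM phosphate (high phosphate) and 5 µM phosphate (low phosphate). Wild type was also grown at low phosphate without added iron and with 100 µM ferrozine, an iron chelator (low iron), and each mutant at low phosphate with 1 mM L-malate. STOP1 is a zinc-finger transcription factor required for expression of ALMT1, which encodes a channel that releases malate from the root. Gene counts came to 29934243, 20619740 and 37189056 in wild type at high phosphate, low phosphate and low iron. They were 25677399, 29722171 and 35960355 in stop1 at high phosphate, low phosphate and with malate, and 31692976, 34149185 and 35771496 in almt1 in the same order.

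Wild type at low phosphate stood apart in library makeup: 44.9% of its recorded reads were counted as aligned at more than 1 place in the genome, against 4.19% to 14.3% in the other libraries, and 1.01% of its gene counts were mitochondrial. The low-iron library and both malate libraries had 2.55% to 2.65% of reads overlapping more than 1 gene, against 0.956% to 1.69% in the other 6. The first principal component, with 46.4% of the variance, placed those 3 libraries at 64.3 to 90.9 and the other 6 at −78 to −8.39. Each of the 3 had a treatment, low iron or malate, that the other 6 lacked, so library set and treatment cannot be told apart in the iron and malate comparisons. Any pair of libraries differed by a chi-square of at least 25.3 per degree of freedom over genes, so none was a copy of another.

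**Figure D1:**
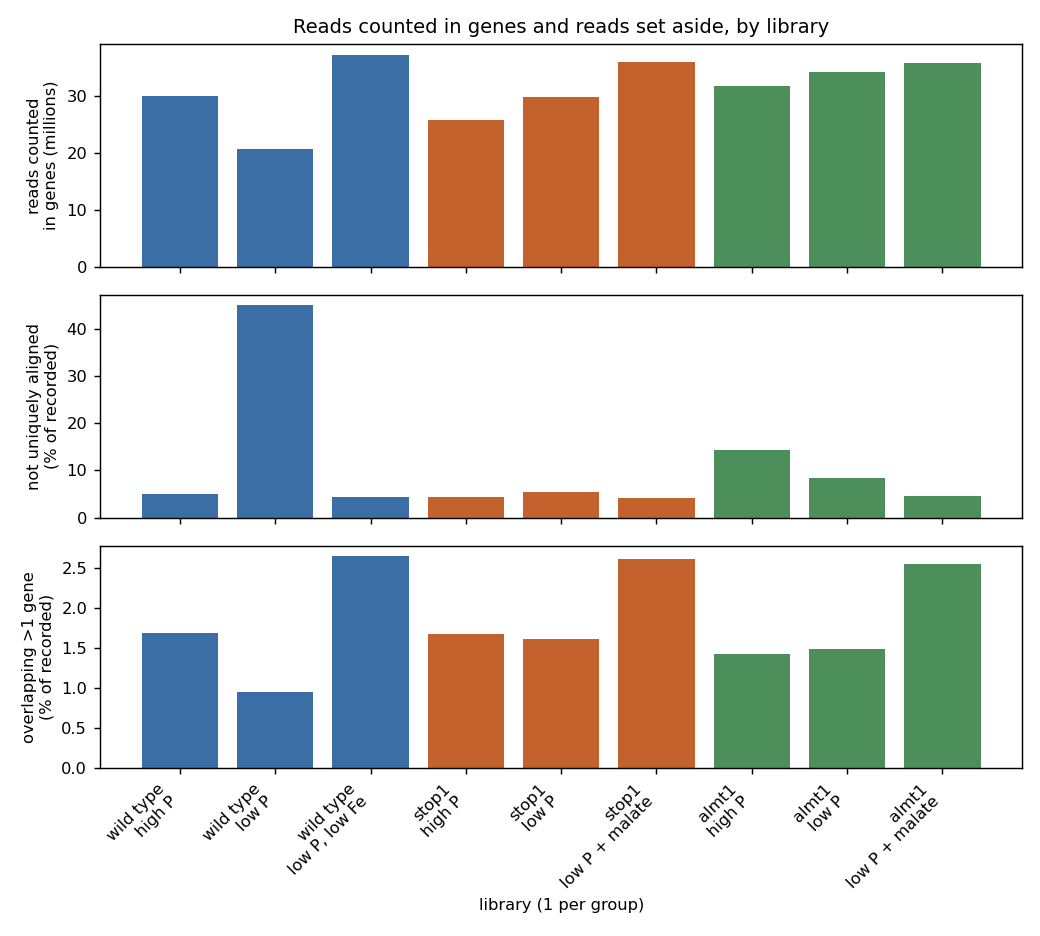
Bars give, for each of the 9 libraries, the counts assigned to genes, the percentage of reads aligned at more than 1 place and the percentage overlapping more than 1 gene. The wild-type low-phosphate library reaches 44.9% in the second panel, and the low-iron and malate libraries reach 2.55% to 2.65% in the third.

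The transcripts of the mutated genes were examined in every library first. STOP1 (AT1G34370) stood at 174, 150 and 105 CPM (counts scaled to a common library size) in stop1 at high phosphate, at low phosphate and with malate. Its level was 158, 150 and 114 CPM in wild type at high phosphate, low phosphate and low iron, and 131, 117 and 103 CPM in almt1. ALMT1 (AT1G08430) had 1, 2 and 0 counts in the stop1 libraries, the last below a floor of 0.0767 CPM, while wild type had 57, 135 and 46.9 CPM and almt1 had 41.6, 97.5 and 15.2 CPM. At high phosphate the log2 ratio of stop1 to wild type for ALMT1 was −10.49, with a 95% counting interval of −15.8 to −8.01. STOP2, a homologue of STOP1, had 0 counts in the stop1 libraries, beside 712 and 556 in wild type at high and low phosphate. CIPK23, a kinase that regulates potassium and nitrate uptake, had 58 counts in stop1 and 2578 in wild type at high phosphate, a log2 ratio of −5.29 (−5.69 to −4.92). The labels name no alleles, and a lesion need not lower its own transcript. STOP1 counts therefore do not check the stop1 label, nor ALMT1 counts the almt1 label. The near absence of ALMT1, which requires STOP1, goes with the stop1 label in all 3 libraries. The names stop1 and almt1 here mean the libraries so labelled, and directions that rest on almt1 rest on its label.

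**Figure D2:**
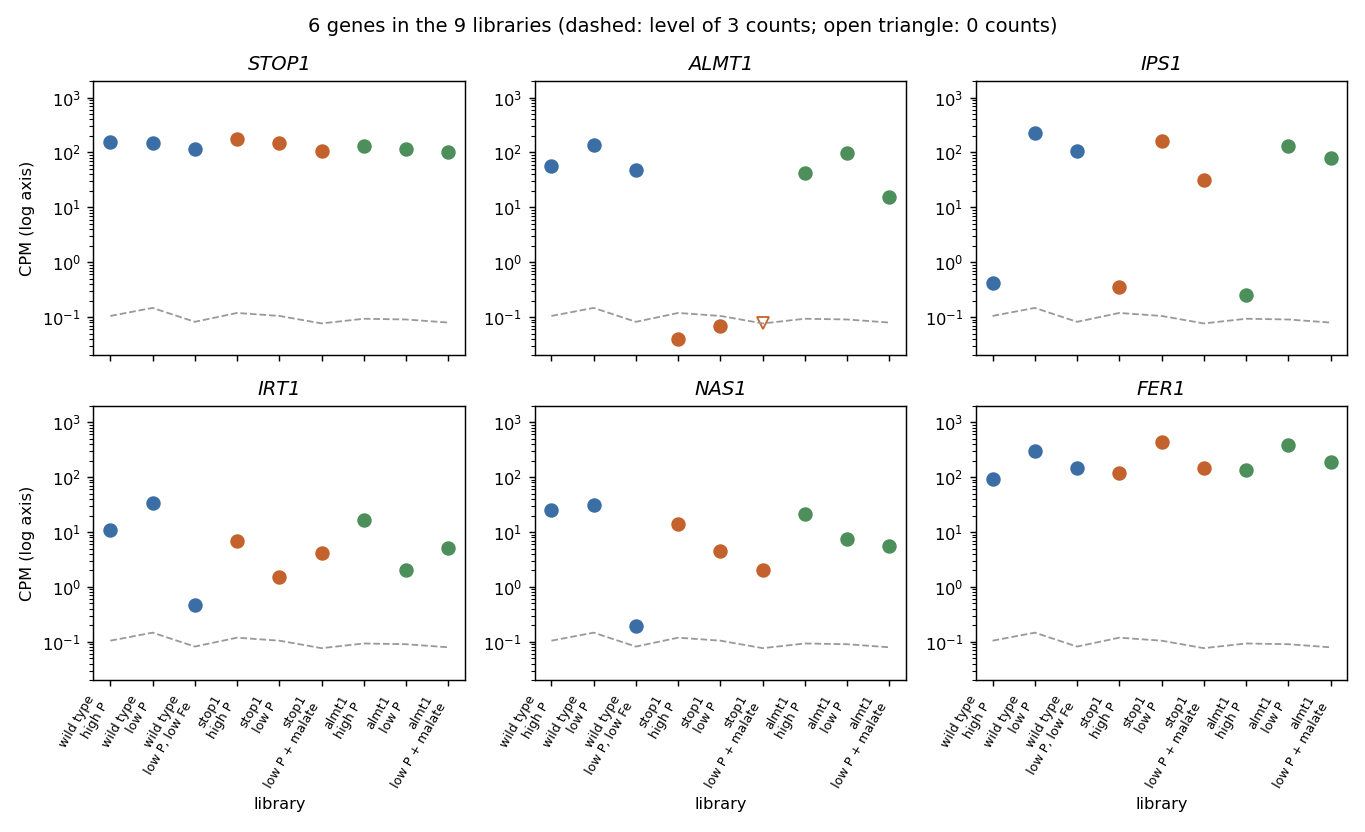
Points show CPM on a log axis for STOP1, ALMT1, IPS1, IRT1, NAS1 and FER1 in each of the 9 libraries, with a dashed line at the level of 3 counts and an open triangle for 0 counts. IPS1 lies at 0.249 to 0.418 CPM in the high-phosphate libraries and at 132 to 224 CPM at low phosphate with iron and without malate.

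The first comparison asked what low phosphate did across the 3 genotypes. Phosphate starvation genes rose: IPS1 (AT3G09922), a non-coding RNA that buffers a phosphate-signalling microRNA, by a log2 fold change of 8.95 (SE 0.16, edgeR adjusted p = 0.00106). So did PECP1 (AT1G17710), a phosphatase that frees phosphate from phospholipid headgroups, by 9.8 (SE 0.56, edgeR adjusted p = 0.0115), and both were higher in 3 of 3 genotypes. SPX3 and SPX1, sensors that restrain the starvation response, rose by 8 (SE 0.41) and 6.18 (SE 0.3). The phosphate transporter PHT1;8 and the purple acid phosphatase PAP11 had 0 counts in the 3 high-phosphate libraries and were at least 268-fold and 198-fold higher at low phosphate, against a floor of 3 counts over the group. Of the 31 measured genes of the systemic phosphate starvation list, 28 rose and 3 did not pass. There were 29 that rose and 1 that fell when adjusted over the list alone (camera adjusted p = 5.3e-26, and adjusted p = 0.457 with an estimated correlation). The sucrose exporters SWEET11 and SWEET12 fell by 5.24 (SE 0.16) and 4.83 (SE 0.41), and AT2G33830, a dormancy-associated protein gene, fell by 4.22 (SE 0.18). Iron storage genes rose in 3 of 8, with the ferritin FER1 at 1.68 (SE 0.14) and the vacuolar iron transporter-like genes VTL1 and VTL2 at 1.94 and 1.78. Of these 8, 6 rose adjusted over the list alone (camera adjusted p = 5.34e-05, adjusted p = 0.457 with an estimated correlation). Root hair genes rose in 1 of 16 (9 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.0111), and hypoxia and heat genes in 2 of 12 (6 adjusted over the list alone; camera adjusted p = 0.00192). Each had an adjusted p = 0.457 with an estimated correlation. Wounding genes rose in 1 of 16 (5 adjusted over the list alone; camera adjusted p = 0.00042) and endodermis and xylem genes passed in 0 of 15, also over the list alone (camera adjusted p = 0.0228, downward). For these lists adjusted p = 0.722 with an estimated correlation. Among 5 measured photosynthesis genes, markers of shoot tissue, LHCB1.3 alone fell, by 2.06 (SE 0.21), and all 5 fell when adjusted over the list alone (camera adjusted p = 4.33e-05, adjusted p = 0.457 with an estimated correlation).

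Across genotypes, edgeR's quasi-likelihood test with genotype as a block called 355 genes higher and 370 lower of 20948 at an adjusted p under 0.05. ALMT1 rose by 1.21 (SE 0.12) in this test, and so did the cell wall protein gene PGIP2, the 2 of 20 listed STOP1 and malate genes that passed (camera adjusted p = 0.296). Of the 20, 3 rose and 2 fell adjusted over the list alone. None of the 15 genes listed for the local response of the tip to low phosphate passed alone in edgeR, though their camera adjusted p was 0.00073 (adjusted p = 0.568 with an estimated correlation). The count of 725 fell to 1 without the stop1 pair and rose to 4629 without the wild-type pair, and DESeq2 called 1982. Wild type at low phosphate, with its 44.9% of multiply aligned reads, is 1 of the 3 low-phosphate libraries here.

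Within the mutants, low phosphate lowered iron uptake genes and raised iron storage genes. IRT1 (AT4G19690), the main ferrous iron transporter of the root, went from 6.76 to 1.54 CPM in stop1 and from 16.6 to 2.05 CPM in almt1 (log2 fold change −2.63, SE 0.29, edgeR adjusted p = 0.0105). The iron-response regulator bHLH39 fell by 2.5 (SE 0.27), and the nicotianamine synthase NAS1 fell by 1.55 (SE 0.21), each lower in 2 of 2 mutants. In all, 11 of 29 measured iron deficiency genes fell and 3 rose, the last being MTP8, AHA7 and F6'H1, which act in metal sequestration, proton release and coumarin synthesis. The numbers were 15 and 4 adjusted over the list alone (camera adjusted p = 0.000174, adjusted p = 0.496 with an estimated correlation). Iron storage genes went the other way, with 5 of 8 rising, among them VTL2 (1.94, SE 0.18), VTL1 (1.8, SE 0.19) and FER1 (1.71, SE 0.16). In this list 7 rose adjusted over the list alone (camera adjusted p = 9.01e-07, adjusted p = 0.496 with an estimated correlation).

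The systemic starvation genes responded in the mutants too, with IPS1 at 9 (SE 0.66) and SPX1 at 6 (SE 0.34). Of 32, 26 rose, and 29 rose and 1 fell adjusted over the list alone (camera adjusted p = 7.3e-22, adjusted p = 0.496 with an estimated correlation). Of the root hair genes, RHD6 and COBL9, a hair-fate regulator and a tip-growth protein, rose by 0.8 and 0.65. Among 16 such genes 9 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.00235, adjusted p = 0.496 with an estimated correlation). ZAT12, a stress-induced zinc-finger gene, rose by 1.6 (SE 0.16) and the expansin EXPA1 by 1.85 (SE 0.21). Of 16 wounding and touch genes 2 rose, also adjusted over the list alone (camera adjusted p = 0.00957, adjusted p = 0.667 with an estimated correlation). Wall extension genes rose in 2 of 15 (3 adjusted over the list alone; camera adjusted p = 0.0118, adjusted p = 0.496 with an estimated correlation). For the local response of the tip 0 of 15 genes passed in edgeR, over all genes or the list alone, and 14 had a positive sign (camera adjusted p = 0.00614, adjusted p = 0.496 with an estimated correlation). Photosynthesis genes fell in 2 of 5 (4 adjusted over the list alone; camera adjusted p = 0.000967), and 1 of 12 hypoxia and heat genes rose, also over the list alone (camera adjusted p = 0.00957); both lists had an adjusted p = 0.496 with an estimated correlation. With only the 6 libraries at high and low phosphate, a fit chosen after seeing the data, 4 of the 15 local genes rose, as did 10 root hair, 6 wall extension, 6 peroxidase, 5 wounding and 5 hypoxia and heat genes. Calls numbered 488 higher and 660 lower of 21229 genes, with 5271 at an unadjusted p under 0.05. Leaving out stop1 at high phosphate, at low phosphate or with malate gave 0, 88 and 5298 calls, and the same for almt1 gave 0, 251 and 5265. A fit of the 6 libraries at high and low phosphate alone, chosen after seeing the data, gave 4631. As pairs of libraries without a replicate check, 1589 genes in stop1 and 1494 in almt1 lay at least 2-fold apart beyond counting error.

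In wild type, low phosphate raised 2553 genes and lowered 2078 in edgeR, among them wound and cell wall genes. TCH3 (AT2G41100), a touch-induced calmodulin-like gene, went from 16.5 to 405 CPM (log2 fold change 4.62, SE 0.57, edgeR adjusted p = 0.0122), and JAZ10, a jasmonate-response repressor, rose by 4.24 (SE 0.48). Of 16 wounding and touch genes 12 rose (13 adjusted over the list alone; camera adjusted p = 2.21e-06, adjusted p = 0.512 with an estimated correlation). The peroxidase PER52 had 0 counts at high phosphate and was at least 471-fold higher at low phosphate, PER37 rose by 3.29 (SE 0.18), and PER69 fell by 2.29 (SE 0.23). In all 5 of 16 cell wall peroxidases rose and 5 fell (6 and 6 adjusted over the list alone; camera adjusted p = 0.86). The expansin EXPA1 rose by 3.94 (SE 0.32) while the xyloglucan-modifying XTH17 fell by 3.48 (SE 0.38) and the pectin methylesterase PME2 fell by 2.49 (SE 0.38). Among wall extension genes 2 of 15 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.353).

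Genes tied to the local response of the tip also moved in wild type. LPR1, a ferroxidase needed for root growth arrest at low phosphate, rose by 1.76 (SE 0.37, edgeR adjusted p = 0.0253), as did the callose synthases CALS3 (0.85, SE 0.19) and CALS12 (1.16, SE 0.23). Of the 15 genes of this list 9 rose, 11 adjusted over the list alone (camera adjusted p = 0.00225, adjusted p = 0.512 with an estimated correlation). Among the STOP1 and malate genes 9 of 20 rose and 1 fell (10 and 1 adjusted over the list alone; camera adjusted p = 0.0556). Members included ALMT1 at 1.24 (SE 0.17), the aluminium-response genes ALS1 and MATE at 1.14 and 1.09, and the nitrate transporter NRT1.1 at −1.2. IRT1 rose by 1.61 (SE 0.35), NAS2 by 2.39 (SE 0.22) and the ferric reductase FRO2 by 1.03 (SE 0.21), whereas FIT, a regulator of iron uptake, fell by 1.22 (SE 0.18). The iron deficiency list had 8 of 29 genes that rose and 2 that fell, also adjusted over the list alone (camera adjusted p = 0.384). FER1, VTL1, VTL2 and YSL1 were the 4 of 8 iron storage genes that rose, also adjusted over the list alone (camera adjusted p = 0.0377, adjusted p = 0.512 with an estimated correlation).

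Growth and cell identity genes in wild type moved in both directions. The mitotic kinase AUR2 fell by 0.97 (SE 0.19) and the cyclin-dependent kinase CDKB1;1 by 0.79 (SE 0.17). Cell cycle genes fell in 8 of 26, and 8 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.132). Within the stem cell niche list WOX5, PLT3 and BBM, regulators of the quiescent centre and meristem, rose by 2 (SE 0.5), 1.84 (SE 0.15) and 1.26 (SE 0.25). Of its 19 genes 3 rose and 2 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.384). The root hair wall proteins LRX1 and LRX2 rose by 3 (SE 0.3) and 2.47 (SE 0.23), with 6 of 16 root hair genes rising (7 adjusted over the list alone; camera adjusted p = 0.0869). Of 15 endodermis and xylem genes CASP5, a Casparian strip protein, fell by 2.86 (SE 0.24) and the xylem protease XCP1 by 1.42 (SE 0.32), the same 2 adjusted over the list alone (camera adjusted p = 0.0556). None of the 4 root cap genes passed in edgeR, and 1 rose adjusted over the list alone (camera adjusted p = 0.478). PCO1, an oxygen-sensing oxidase, and the sucrose synthase SUS1 rose by 2.05 (SE 0.43) and 1.86 (SE 0.26). With LBD41 they were the 3 of 12 hypoxia and heat genes to rise (6 adjusted over the list alone; camera adjusted p = 0.022, adjusted p = 0.512 with an estimated correlation). Photosynthesis genes fell in 3 of 5, also adjusted over the list alone (camera adjusted p = 0.0117, adjusted p = 0.512 with an estimated correlation). Of 8 reference genes only UBC21 fell in edgeR, by 0.83 (SE 0.2; camera adjusted p = 0.818). In this wild-type test 28 of 32 systemic starvation genes rose and 4 did not pass, and 30 rose adjusted over the list alone (camera adjusted p = 2.32e-14, adjusted p = 0.512 with an estimated correlation). AT2G04460 had 0 counts at high phosphate and was at least 2470-fold higher.

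Each wild-type library stands alone in this test and was assumed to vary as the mutants do, and the low-phosphate one is the library with 44.9% multiply aligned reads. Counts of calls without stop1 at high phosphate, at low phosphate and with malate were 1516, 2905 and 9085, and for almt1 1434, 2814 and 9066. The 6 libraries at high and low phosphate alone, a fit chosen after seeing the data, gave 8581. The list that changed most was endodermis and xylem, with 11 of 15 genes falling there in place of 2, while 12 local genes and 7 hypoxia and heat genes rose and 6 wall extension genes fell.

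Whether wild type responded differently from the mutants was tested directly. The response of IRT1 was more positive in wild type by a log2 difference of 4.24 (SE 0.46, edgeR adjusted p = 0.0226), since it rose there and fell in 2 of 2 mutants. NAS2 and FRO2 differed the same way, by 2.44 (SE 0.27) and 1.99 (SE 0.26). With IRT1 they were the 3 iron deficiency genes of 29 that passed (9 adjusted over the list alone; camera adjusted p = 0.000521, adjusted p = 0.691 with an estimated correlation). JAZ10 (3.92, SE 0.58) and JAZ1 (1.69, SE 0.24) passed among 16 wounding genes (7 adjusted over the list alone; camera adjusted p = 0.00012, adjusted p = 0.691 with an estimated correlation). PDF1 (AT2G42840), a protodermal protein, went from 1.22 to 47.1 CPM in wild type, from 0.633 to 0.489 in stop1 and from 0.685 to 0.211 in almt1, a difference of 6.21 (SE 0.63). GRP5, a glycine-rich wall protein, and PDF2 (AT4G04890), an epidermal homeobox regulator, differed by 6.61 (SE 0.81) and 6.32 (SE 0.75). In the other direction AGP30, a root arabinogalactan protein, went from 118 to 5.89 CPM in wild type and stayed at 131 and 143 in stop1 and 103 and 87.6 in almt1 (−4.28, SE 0.46). XTH17 differed by −3.49 (SE 0.44) and CASP5 by −2.15 (SE 0.28).

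For systemic starvation genes 0 of 32 passed in edgeR, over all genes or the list alone, and 31 had a positive sign (camera adjusted p = 0.00341, adjusted p = 0.729 with an estimated correlation). For the local response of the tip 0 of 15 passed, also over the list alone (camera adjusted p = 0.0252, adjusted p = 0.691 with an estimated correlation). The STOP1 and malate list had the same camera values, with 0 of 20 passing (2 over the list alone). Cell cycle genes passed in 0 of 26, also over the list alone (camera adjusted p = 0.00924 for a more negative response, adjusted p = 0.691 with an estimated correlation). Of 15 wall extension genes XTH17 passed (1 more positive and 3 more negative over the list alone; camera adjusted p = 0.0194, adjusted p = 0.691 with an estimated correlation). With the 6 libraries at high and low phosphate alone, a fit chosen after seeing the data, more list genes passed. A more positive response in wild type was called for 11 systemic, 6 local, 7 STOP1 and malate, 10 iron deficiency and 8 wounding genes, and a more negative one for 8 endodermis and xylem, 6 wall extension and 5 cell cycle genes. In total 146 genes had a more positive and 119 a more negative response in wild type. That count was 0 in edgeR without any 1 of the high- or low-phosphate libraries of stop1 or almt1. It was 4641 and 4602 without the malate library of stop1 and of almt1. The spread of this fit comes from disagreement of stop1 and almt1 across their conditions, malate included, so unequal malate responses enter it. Whether that alone raised the counts was not tested. DESeq2 called 959, and the 6 libraries at high and low phosphate alone gave 3764, which included all 265. Every one of the 265 calls rests on the wild-type low-phosphate library and its 44.9% multiply aligned reads.

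**Figure D3:**
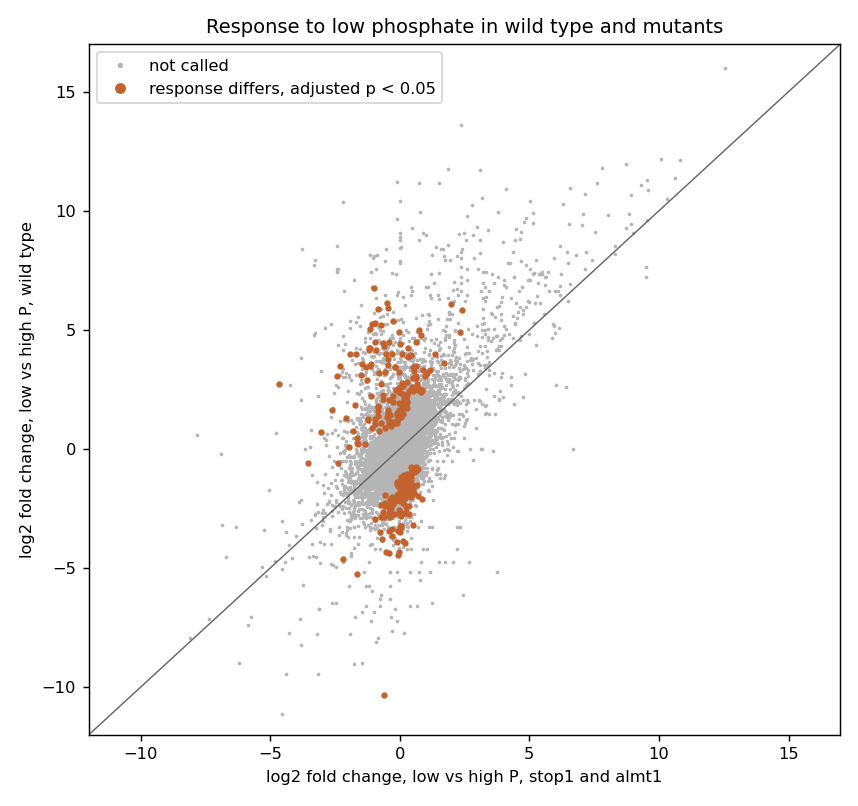
Each point is a gene, with its log2 fold change at low against high phosphate in stop1 and almt1 on the horizontal axis and in wild type on the vertical axis, and the line marks equal responses. Orange points are the 265 genes whose response differed at an edgeR adjusted p under 0.05.

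Set against wild type at low phosphate, the mutants had less transcript of IRT1, TCH3 and JAZ10. IRT1 was lower by a log2 fold change of −4.23 (SE 0.51, edgeR adjusted p = 0.0119) and bHLH39 by −1.93 (SE 0.31), lower in 2 of 2 mutants. Of the iron deficiency list 4 of 29 genes fell (9 adjusted over the list alone; camera adjusted p = 0.000362, adjusted p = 0.609 with an estimated correlation). Systemic starvation genes had a negative sign in 32 of 32, but 1 passed and 0 over the list alone (camera adjusted p = 0.000362, adjusted p = 0.668 with an estimated correlation). Of 26 cell cycle genes 1 rose and 24 had a positive sign (5 rose adjusted over the list alone; camera adjusted p = 0.000362, adjusted p = 0.609 with an estimated correlation). CASP5 alone rose of 15 endodermis and xylem genes (5 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.00968, adjusted p = 0.668 with an estimated correlation). None of the 15 local genes passed, over all genes or the list alone (camera adjusted p = 0.0286, downward, adjusted p = 0.609 with an estimated correlation). The same held for the 20 STOP1 and malate genes (camera adjusted p = 0.0429, downward, adjusted p = 0.668 with an estimated correlation). Wounding genes fell in 9 of 16, including TCH3 (−2.9, SE 0.38) and JAZ10 (−3.12, SE 0.44), and 10 fell adjusted over the list alone (camera adjusted p = 2.41e-05, adjusted p = 0.609 with an estimated correlation). Cell wall peroxidases went both ways: PER52 was at −7.14 (SE 1.12), PER33 at −4.32 (SE 0.44), PER37 at −2.8 (SE 0.45) and PER3 at 1.18 (SE 0.18). Of 16, 3 fell and 1 rose (4 and 3 adjusted over the list alone; camera adjusted p = 0.847). XTH17 (3.49, SE 0.34), PME2 (2.54, SE 0.4) and CASP5 (2.5, SE 0.33) were higher in the mutants. The defensin-like gene LCR67 and the ABC transporter ABCG39 had 0 counts in the mutants at low phosphate and were at least 269-fold and 150-fold lower than in wild type. Calls numbered 449 higher and 952 lower. DESeq2 gave 1058 and 1206, 46.7% higher against 32%. The count of 1401 became 888, 230, 884 and 130 without stop1 at high phosphate, stop1 at low phosphate, almt1 at high phosphate and almt1 at low phosphate, and it rests on the same wild-type library with 44.9% multiply aligned reads.

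At high phosphate edgeR called 0 genes between the mutants and wild type, with 893 at an unadjusted p under 0.05; DESeq2 also called 0, with 504. No list had a camera adjusted p under 0.297, and none of the 261 listed genes passed, over all genes or over a list alone. As single libraries, with no replicate check, 245 genes were at least 2-fold higher and 407 lower in stop1 than in wild type. In almt1 244 were higher and 151 lower, which became 300 and 105 (74.1% higher against 61.8%) when scaled by library size alone. The median log2 ratio of the STOP1 and malate list was −0.75 for stop1 against wild type, at percentile 0 of 10000 matched random lists, and −0.04 for almt1, at percentile 40.77. The almt1 library at high phosphate has 14.3% multiply aligned reads, and AT2G01021, a gene of the ribosomal RNA region, was at a log2 ratio of 2.59 (2.54 to 2.65) there. Between almt1 and stop1, 790 genes were 2-fold apart at high phosphate, 799 at low phosphate and 934 with malate (804 higher in almt1 and 130 lower), with ALMT1, STOP2 and CIPK23 among the 5 highest at low phosphate and with malate.

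The malate libraries asked what external malate did to mutants at low phosphate. Iron storage genes fell in 6 of 8: VTL5 by 2.39 (SE 0.28, edgeR adjusted p = 0.00771), VTL1 by 1.94 (SE 0.19) and FER1 by 1.33 (SE 0.16), each lower in 2 of 2 mutants. Adjusted over the list alone 6 fell (camera adjusted p = 0.0156, adjusted p = 0.651 with an estimated correlation). Phosphate starvation genes fell in 19 of 32 and rose in 1, with SPX3 at −3.19 (SE 0.66) and the transcription factor WRKY75 at −2.21 (SE 0.29). Of the 32, 22 fell and 1 rose adjusted over the list alone (camera adjusted p = 6.45e-05, adjusted p = 0.673 with an estimated correlation). The mutants were unequal: as pairs without a replicate check, 26 were at least 2-fold lower and 0 higher in stop1, and 8 lower and 2 higher in almt1. The title of the stop1 malate sample reads as high phosphate, against its characteristics, and this doubt bears on these genes. IPS1 was at 30.9 CPM in it, beside 0.356 and 162 CPM in stop1 at high and low phosphate. PCO1 and PCO2 rose by 3.2 (SE 0.32) and 2.41 (SE 0.32) and the heat shock factor HSFA2 by 1.74 (SE 0.31). Hypoxia and heat genes rose in 6 of 12 (7 adjusted over the list alone; camera adjusted p = 0.00762, adjusted p = 0.651 with an estimated correlation). The mitotic activator CDC20.1 rose by 1.2 (SE 0.11) and the replication helicase subunit MCM4 by 0.85 (SE 0.13). CDC20.1 stood at 59.5 and 50.4 CPM in stop1 and almt1 with malate and at 55.3 CPM in the low-iron library. Library set and treatment cannot be told apart for it. Of 26 cell cycle genes 13 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.0167, adjusted p = 0.651 with an estimated correlation). PLT3, PLT2, BBM and SCR were among 7 of 19 stem cell niche genes that rose, with 1 falling (8 and 1 adjusted over the list alone; camera adjusted p = 0.126).

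Iron deficiency genes moved both ways with malate: bHLH39 (1.86, SE 0.27) and IRT1 (1.4, SE 0.29) were among 9 that rose and MTP8 (−3.56, SE 0.56) and FIT (−0.87, SE 0.12) among 6 that fell, also adjusted over the list alone (camera adjusted p = 0.154). Of the STOP1 and malate list 9 of 20 fell, with the malic enzyme NADP-ME1 at −4.41 (SE 0.44) and ALMT1 at −2.68 (SE 0.18). There were 10 that fell and 1 that rose adjusted over the list alone (camera adjusted p = 0.00762, adjusted p = 0.651 with an estimated correlation). The ALMT1 value rests on almt1, where it went from 97.5 to 15.2 CPM. In other lists PER37 rose by 2.33 (SE 0.12), CALS3 by 0.97 (SE 0.14) and the root cap regulator FEZ by 1.55 (SE 0.24), and CASP5 fell by 1.28 (SE 0.15). Of 16 peroxidases 2 rose and 5 fell, with PER4 at −2.18 (SE 0.2). Local genes rose in 4 of 15 and fell in 2, with CLE14 at −1.29 (SE 0.27). Wall extension genes rose in 2 of 15 and fell in 5. CASP5 was among 3 of 15 endodermis and xylem genes that fell (2 adjusted over the list alone; camera adjusted p = 0.0276, adjusted p = 0.717 with an estimated correlation). Beyond the lists, the chitinase-family gene AT2G43620 rose by 7.32 (SE 0.55) and the expansin EXPA12 by 3.85 (SE 0.24). The late embryogenesis protein LEA4-5 went from 71.4 to 0.256 CPM in stop1 and from 18.2 to 0.318 in almt1 (−7.16, SE 0.56). The linker histone HIS1-3 fell by 4.53 (SE 0.23) and the drought-related homeobox gene HB-12 by 4.54 (SE 0.83). Among 8 reference genes 4 fell, UBQ10 by 1.16 (SE 0.19) the most. UBQ10 was at 637 and 938 CPM in stop1 and almt1 with malate, and at 801 CPM in the low-iron library.

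With malate 3649 genes were higher and 4114 lower in edgeR. The count of 7763 was 4205, 69, 4131 and 647 without stop1 at high phosphate, stop1 at low phosphate, almt1 at high phosphate and almt1 at low phosphate. As pairs without a replicate check, 1301 genes were 2-fold higher and 2940 lower in stop1, and 920 and 1523 in almt1. Scaling by library size alone gave 2043 and 2392 (46.1% higher against 30.7%) and 1267 and 1183 (51.7% against 37.7%).

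The library labelled low iron was set against wild type at low phosphate with iron. Its label is taken as given, and each low-iron value depends on it. Genes that roots raise when iron is short went the other way: of the iron deficiency list 0 rose, and iron uptake genes fell. IRT1 went from 33.8 to 0.465 CPM (log2 fold change −6.17, SE 0.47, edgeR adjusted p = 0.00172) and NAS1 from 31.5 to 0.191 CPM (−7.34, SE 0.45), and FRO2 fell by 2.25 (SE 0.22). In all 14 of 29 fell and 15 did not pass (15 fell adjusted over the list alone; camera adjusted p = 0.000888, adjusted p = 0.645 with an estimated correlation). VTL5, VTL1, FER1 and VTL2 fell, by 3.5 (SE 0.41), 2.62 (SE 0.28), 1.05 (SE 0.23) and 0.89 (SE 0.25), while the ferritins FER3 and FER2 rose by 0.78 and 0.65, also adjusted over the list alone (camera adjusted p = 0.156). STOP1 and malate genes fell in 14 of 20 (15 adjusted over the list alone; camera adjusted p = 9.77e-05, adjusted p = 0.645 with an estimated correlation), with ALMT1 at −1.52 (SE 0.18). Phosphate starvation genes fell in 12 of 32, SPX3 by 4.88 (SE 0.96) and WRKY75 by 3.4 (SE 0.43), and 14 fell adjusted over the list alone (camera adjusted p = 9.77e-05, adjusted p = 0.675 with an estimated correlation). TCH3 fell by 5.21 (SE 0.59), among 7 of 16 wounding genes that fell (8 adjusted over the list alone; camera adjusted p = 0.00015, adjusted p = 0.645 with an estimated correlation).

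Other genes rose with low iron. CDC20.1 rose by 1.33 (SE 0.15) among 13 of 26 cell cycle genes that rose and 1 that fell (17 and 1 adjusted over the list alone; camera adjusted p = 9.77e-05, adjusted p = 0.645 with an estimated correlation). HSFA2, HSP90.1 and HSP101, of the heat shock response, rose by 3.42 (SE 0.48), 2.54 (SE 0.18) and 1.87 (SE 0.17), while SUS1 fell by 2.23 (SE 0.26). CASP5 and CASP4 rose by 3.77 (SE 0.24) and 2.59 (SE 0.37), XTH17 by 3.46 (SE 0.38), and the flavonoid hydroxylase TT7 and the glutathione transferase GSTF12, of anthocyanin synthesis and transport, by 4.12 (SE 0.24) and 4.61 (SE 0.55). The root hair genes CSLD3 and COBL9 rose by 1.01 (SE 0.16) and 1.17 (SE 0.18), with 5 of 16 rising, also adjusted over the list alone (camera adjusted p = 0.0166, adjusted p = 0.645 with an estimated correlation). GRP5, PDF1 and the lipid transfer protein LTP2 had 0 counts with low iron and were at least 685-fold, 575-fold and 345-fold lower than at low phosphate with iron. Calls numbered 2649 higher and 3851 lower, each resting on 1 library a side, and the comparison library has 44.9% multiply aligned reads. Without stop1 at high phosphate, stop1 with malate, almt1 at high phosphate and almt1 with malate the total of 6500 was 3356, 10168, 3337 and 10161.

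**Figure D4:**
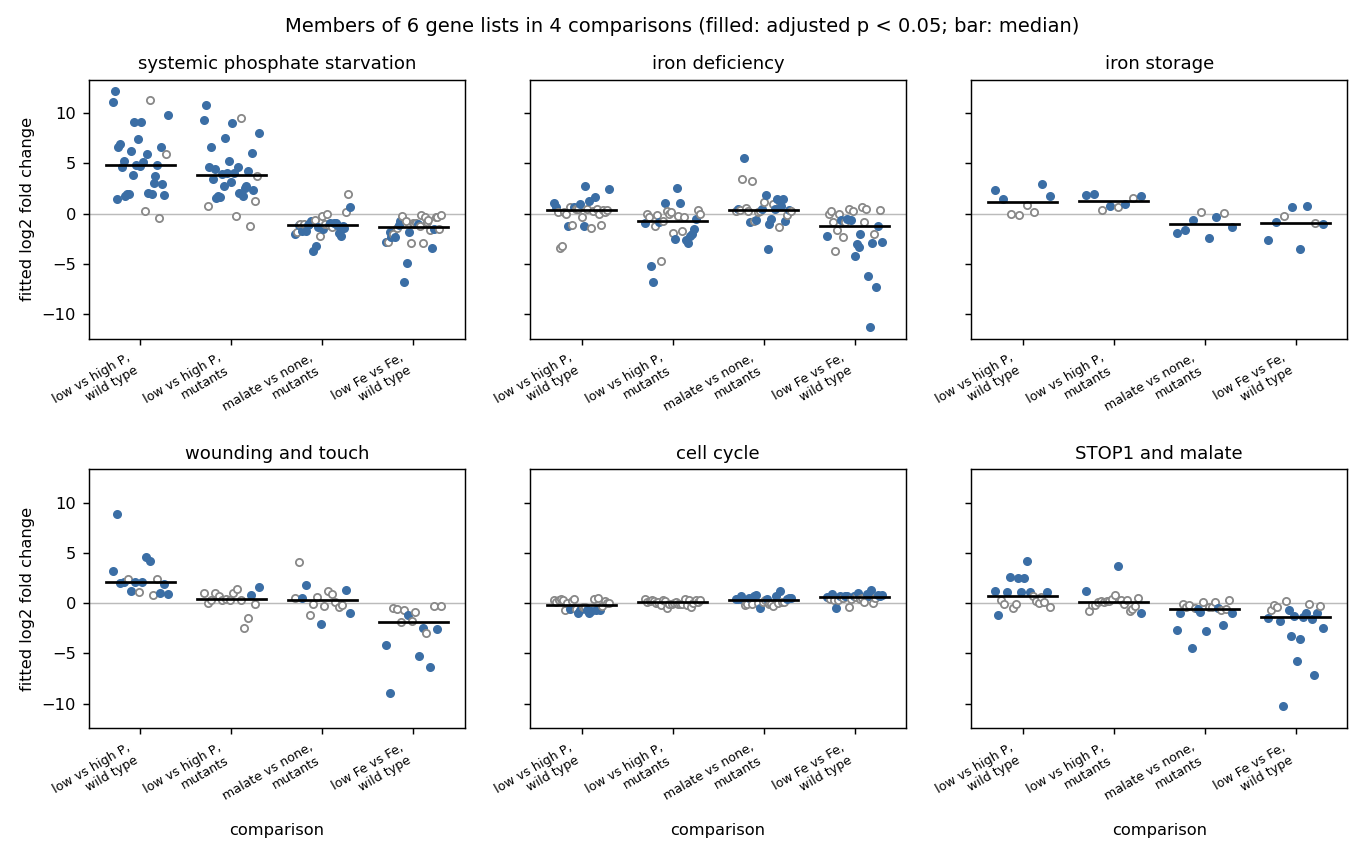
Points are the measured genes of 6 lists, with the log2 fold change on the vertical axis in 4 comparisons, filled where the edgeR adjusted p is under 0.05, and bars mark medians. Iron deficiency genes fall with low phosphate in 11 of 29 in the mutants and with low iron in 14 of 29 in wild type.

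The study's design also asks whether malate moved mutant genes as low phosphate moved wild-type genes. Calls shared by these comparisons, which have no library in common, were 984 higher in both and 1161 lower in both, where independent lists would share 439 and 403. Another 311 genes were higher at low phosphate in wild type and lower with malate, and 37 the reverse. Over 21229 genes the log2 ratios of wild type at low against high phosphate had a Pearson r of 0.0727 with those of malate in stop1 and of 0.292 with those in almt1. Spearman's rho was higher, 0.252 and 0.425. Among genes, which are not independent replicates, low phosphate ratios had r of 0.757 (rho 0.63) between stop1 and almt1, 0.602 (rho 0.524) between wild type and stop1 and 0.456 (rho 0.289) between wild type and almt1, and malate ratios 0.755 (rho 0.766) between the mutants. Low iron and malate ratios had r of 0.399 (rho 0.395) in stop1 and 0.233 (rho 0.305) in almt1. The wild-type phosphate and iron ratios share the low-phosphate library and correlated at −0.521, beside −0.531 simulated for unchanged groups; their covariance was −0.798 against −0.0809 simulated.

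One comparison was added after the data were seen, within the 3 libraries that share a high percentage of reads overlapping more than 1 gene: the malate-treated mutants against low-iron wild type. The glycine-rich protein GRP9 went from 0.301 CPM in wild type to 22.5 in stop1 and 27.9 in almt1 (log2 fold change 6.37, SE 0.53, edgeR adjusted p = 0.0217), and EXPA12 was higher by 4.2 (SE 0.6). CASP5 was lower in the mutants by −2.55 (SE 0.25), AGP30 by −2.54 (SE 0.31) and the fatty acyl reductase CER4 by −2.61 (SE 0.23). There were 75 genes higher and 87 lower of 21229. None of the root hair genes passed over all genes in edgeR, but 9 of 16 fell adjusted over the list alone (camera adjusted p = 5.7e-07, adjusted p = 0.853 with an estimated correlation). CASP5 was 1 of 7 endodermis and xylem genes that fell adjusted over the list alone (camera adjusted p = 0.000134, adjusted p = 0.853 with an estimated correlation). Systemic starvation genes passed in 0 of 32 (3 fell adjusted over the list alone; camera adjusted p = 0.0011) and 1 of 29 iron deficiency genes rose (4 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.0278). Both had an adjusted p = 0.853 with an estimated correlation. Malate and iron supply differ here as well as genotype. By genotype AGP30 went the other way at low phosphate alone, where it was lower in wild type than in the mutants. The total of 162 was 2, 14, 2, 14 and 416 without stop1 at high phosphate, stop1 at low phosphate, almt1 at high phosphate, almt1 at low phosphate and almt1 with malate. DESeq2, RLE size factors, no filter, a filter of 1 CPM and a mutant genotype term gave 1019, 319, 329, 257 and 465.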

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

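Of the tests below, only that of multiply aligned reads was set before its result was seen; the others were chosen after the results were seen. For 3 of them the bound was also replaced after its outcome was seen. For the counts of genes that went in opposite directions the earlier bound, a share of 5%, would have argued against a library set, and the number for independent lists took its place because genes picked for opposite directions pass a small share too easily. For a fault of the wild-type low-phosphate library the earlier bound, a share of matching signs above that of all genes, would have argued against it. It was replaced because such a match is a reversal by genotype. Under the bound that took its place the test cannot decide, and no conclusion is drawn from the match below.

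The response to low phosphate differed between wild type and the mutants in 265 genes by a test of the difference in edgeR. The largest positive log2 differences (wild type minus mutants) were at AT1G26250 (7.4), AT5G52670 (6.73), GRP5 (6.61), the peroxidase gene AT4G08780 (6.36), the epidermal regulator PDF2 (6.32), the protodermal gene PDF1 (6.21), AT4G29020 (6.2), the senescence regulator NAP (5.92), AT3G23450 (5.88) and the pyrimidine catabolism gene PYD4 (5.77). The most negative were at AT4G37950 (−9.74, a fitted value that is no bound, since wild type had 0 counts at low phosphate), AGP30 (−4.28), AT5G46900 (−4.14), AGP13 (−4), AT4G25830 (−3.94), the brassinosteroid oxidase BR6OX1 (−3.81), ACP5 (−3.77), AT4G25250 (−3.72), AT2G15960 (−3.61) and XTH17 (−3.49). Without any 1 of the high- or low-phosphate libraries of stop1 or almt1 edgeR called 0 genes, and without the malate library of stop1 or of almt1 it called 4641 or 4602.

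Some library summaries lay above the highest of the 3 high-phosphate libraries. In wild type at low phosphate 44.9% of reads aligned at more than 1 place and 4.24% overlapped no gene. Reads overlapping more than 1 gene were 2.65% in the low-iron wild-type library, 2.61% in stop1 with malate and 2.55% in almt1 with malate. No group had enough libraries to test for a library far from its own group.

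The 265 genes all rest on the wild-type low-phosphate library. A proportional effect of multiply aligned reads would give almt1 against stop1 at high phosphate, with 0.249 of the wild-type gap in that share, a signed median of 0.54. It was 0.142 (bootstrap SE over genes 0.0317) against 2.17 in the wild-type pair, below the value set beforehand. The genes were called from these same libraries, for a large wild-type difference beside a small disagreement of stop1 and almt1. That selection pulls both medians this way, so the test cannot decide and multiply aligned reads stay open as a cause. Aerial tissue would raise photosynthesis genes, whose median was −1.45 in the wild-type pair. It was −1.77 in the stop1 pair and −1.45 in the almt1 pair. The fall was common to the genotypes, so its sign does not test for aerial tissue in wild type. For a fault of that library alone, signs were compared with a contrast that does not use it, malate mutants minus low-iron wild type. The sign of wild type minus mutants in the response matched there in 94.3% of the genes (250 of 265), against 62.8% of all genes. Of the 265, 64 were called with matching signs and 0 with opposite ones, where independent lists would share 1. By genotype that match is a reversal, as at AGP30, lower in wild type at low phosphate and lower in the mutants with malate. None of the genes was called in the original sense by genotype in that comparison. The same held at high phosphate, but there the fit called 0 of all 21229 genes, so it has no bearing on these. With malate, of the 146 genes more positive in wild type 66 rose and 20 fell in the mutants. Of the 119 more negative, 95 fell and 1 rose. Independent lists would give 25.1, 28.3, 23.1 and 20.5, but the mutants' low-phosphate libraries serve both contrasts. Because the match is a reversal by genotype, it cannot tell a fault of the wild-type low-phosphate library from other causes. Such a fault, a genotype difference and effects of malate or iron supply stay open and untested.

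The low-iron and malate libraries shifted many genes alike: 2632 were called the same way in both contrasts, where independent lists would share 1202. A second library set could give this, and so could a real effect of the treatments; for these genes the explanations cannot be told apart, since no library of either kind was made without its treatment. Another 584 genes, 18.2% of the 3216 called in both, went in opposite directions; independent lists would give 1175, so this number excludes no explanation, and a library set stays open for them too.

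Iron deficiency genes fell with low iron, 14 of 29, where iron limitation would be thought to raise them, so the low-iron label itself is in doubt. A second library set stays open for some members. IRT1 (−6.17 with low iron, 1.4 with malate), bHLH39 and FPN2, the 3 that rose with malate, are near the 2.41 that independent lists would give. An equal shift in both contrasts would not move them in opposite directions. FIT, F6'H1, NAS1, MTP8 and MTP3, the 5 that fell with malate too, go with its direction. Their sizes were alike for FIT (−0.61, −0.87), F6'H1 (−0.57, −0.67) and MTP8 (−3.33, −3.56). They were unlike for NAS1 (−7.34, −0.76) and MTP3 (−2.05, −1.01). Of the 14 genes that fell with low iron, 6 were not called with malate. Iron being available to the plants of that library, through a wrong label or otherwise, could lower them as well, and this stays open: FER3 (0.78) and FER2 (0.65) rose with low iron, which goes with it, and 4 iron storage genes fell, which goes against it, but all 4 also fell with malate, so that 0 fell with low iron and not with malate. A biological effect of low iron and low phosphate together was not tested.

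For low against high phosphate over 3 genotypes, 1 of the 10 splits of the 6 libraries into 3 and 3, the real one, gave 725 genes in edgeR. The highest other count was 0, with up to 4535 genes at an unadjusted p under 0.05 against 5177 for the real split. Genotype was a block, so the 6 splits with both libraries of a genotype on 1 side compare a single genotype's pair, and 4535 is the wild-type pair alone. Only 4 splits part every genotype, and the highest of the other ones among these had 421 genes at an unadjusted p under 0.05. The 10 splits are too few for a share under 0.05.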

How the results depend on the processing

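The fits of 6 libraries, the comparison of malate mutants with low-iron wild type and the shared calls were chosen after seeing the data, and the other alternatives before. No named gene's call, list call or correlation changed sign under the alternatives run. The balance of higher and lower calls did turn: from 37.7% to 51.7% higher for malate in the almt1 pair and from 50.7% to 48.3% for low phosphate in the stop1 pair with library size alone. It turned from 55.1% to 46.4% with DESeq2 and 45.7% without the genotype term for the response difference, and with a filter of 1 CPM from 47% to 51.5% for malate and to 2184 higher and 2185 lower for low phosphate in wild type. It turned as well over 3 genotypes without 1 mutant genotype, and without single libraries in the mutants, and for malate mutants against low-iron wild type. Counts of calls stayed within 1.5 times the value reported in 47 cases and moved further in 54 for fits, and in 47 and 5 for pairs. Named genes kept their side of the threshold in 1458 cases and lost their call in 294, and list calls kept theirs in 203, with 1 lost and 4 gained.

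Leaving out single libraries gave 0 to 5298 calls for low phosphate in the mutants, 1434 to 9085 in wild type, 0 to 4641 for the response difference, 69 to 10206 for malate, 3337 to 10168 for low iron, 130 to 1476 for mutants against wild type at low phosphate, 0 to 0 at high phosphate, and 2 to 416 for malate mutants against low-iron wild type. Over 3 genotypes, leaving out 1 genotype gave 1 to 4629. Fewer libraries leave fewer degrees of freedom. In the 9-library fits the malate libraries enter the spread of every contrast. Whether this is why omitting a malate library raised counts was not tested.

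DESeq2 called 1982 genes over 3 genotypes, 959 for the response difference, 2264 for mutants against wild type at low phosphate and 1019 for malate mutants against low-iron wild type. RLE factors gave 514 and 319 for the response difference and the last comparison, and no filter 548 and 329; a filter of 1 CPM gave 257 for the last. Changing the genotype term gave 1160 over 3 genotypes, 105 for the response difference, 2222 and 2 for mutants against wild type at low and high phosphate, and 465 for the last. The cause was not tested. The 6 libraries at high and low phosphate alone gave 4631 in mutants, 8581 in wild type and 3764 for the response difference, and for list calls turned 1 off, iron storage in wild type (camera adjusted p = 0.0519), and 4 on; the cause was not tested.

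The 64 calls with matching signs in the response difference (wild type minus mutants) and in malate mutants minus low-iron wild type became 287 with DESeq2, 117 with RLE factors, 114 without a filter, 113 with the genotype term in both and 115 with 6 libraries; the cause was not tested. Asking for 50 counts left fewer genes: 353 for stop1 and 149 for almt1 against wild type at high phosphate, and 446, 435 and 582 for almt1 against stop1 at high phosphate, low phosphate and with malate. With genes of at least 5 CPM, fewer in number, r was 0.208 and 0.438 between wild-type low phosphate and malate in stop1 and almt1, and 0.349 between low iron and malate in almt1. The spread behind each fit rests on 2 or 3 residual degrees of freedom. Depth sets the floor of 0.0767 to 0.147 CPM.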

Other observations

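Both gene groups below were chosen after their values were seen, and all tests on them came later. No test of either group as a set is given, because its genes were picked for their movement.

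Genes of aliphatic glucosinolate synthesis, which makes sulphur-rich defence compounds from methionine, rose at low phosphate in wild type in 16 of 17 (median log2 fold change 2.91, edgeR). BCAT4, an aminotransferase at the start of the pathway, went from 6.48 to 365 CPM in wild type, from 2.57 to 10 in stop1 and from 5.38 to 35.8 in almt1. MAM3, a chain-elongating synthase, went from 59.8 to 353 CPM in wild type and stood at 62.3 and 57.7 in stop1 and 61.3 and 62.7 in almt1. Of the 17, 8 had a larger response in wild type than in the mutants by the test of the difference, and 7 rose in the mutants (median 0.76). With low iron 16 fell (median −6.06), BCAT4 to 0.191 CPM and MAM3 to 1.01 CPM, and with malate 9 fell (median −0.55). The rise in wild type, the larger response there and the fall with low iron all use the wild-type low-phosphate library. As contrasts they are therefore not independent. The low-iron library was also below wild type at high phosphate, with BCAT4 at 0.191 against 6.48 CPM and MAM3 at 1.01 against 59.8 CPM. In malate mutants against low-iron wild type, which does not use that library, 16 of the 17 had a positive sign and 1 a negative one (median 2.99). Malate and iron supply differ there as well as genotype. At high phosphate 0 of the 17 differed between mutants and wild type in edgeR. That fit called 0 of all 21229 genes, so this does not show equal levels.

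Genes of the epidermal surface and cuticle rose in wild type at low phosphate in 11 of 18 and fell in 1 in edgeR. The epidermal regulator ATML1 rose by 3.23 (SE 0.61), PDF1 by 5.27 (SE 0.45) and the lipid transfer gene LTP2 by 3.17 (SE 0.26), while the wax synthesis gene CER1 fell by 1.78 (SE 0.27). In mutants against wild type at low phosphate 10 fell and 1 rose, and with low iron 14 fell and 1 rose. Each of these contrasts uses the wild-type low-phosphate library, with its 44.9% of multiply aligned reads. In malate mutants against low-iron wild type, which does not use it, 13 of the 18 had a positive sign and 5 a negative one (median 1.32). Malate and iron supply differ there as well as genotype. At high phosphate, also without the wild-type low-phosphate library, 0 of the 18 passed between mutants and wild type, and 13 had a negative sign (median −0.17). That fit called 0 of all 21229 genes, so this does not show equal levels.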
